A study of Rattus norvegicus with 4 samples.

How the data were processed

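The series holds 4 strand-specific RNA-seq libraries of neonatal rat ventricular cardiomyocytes from postnatal day 2 Sprague-Dawley rats. Per the labels' protocols, isolated cells were first left to settle so that non-cardiomyocytes would attach and be removed. The remaining cells were cultured in serum-containing medium, and total RNA was depleted of ribosomal RNA before library preparation. There were 2 libraries of cells treated with phenylephrine (PE), an agonist of adrenergic receptors, at 20 µM for 24 h, and 2 libraries of control cells. The groups were taken from the treatment label of each sample, because the protocol text names PE for every sample. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

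The first deposited table gives raw counts per gene for each library, which the authors made from their reads. Cutadapt 2.0, STAR 2.4.2a and featureCounts 1.6.4 are named with the build Rnor_6.0, per the submitters' processing notes. Their order, parameters, annotation release and strand setting are not given in the sources used here. Reads of overlapping or antisense genes were therefore treated as uncertain, as were reads shared between near-identical copies such as the actins, tubulins, histones, ribosomal protein genes and the Myh6 and Myh7 pair. The second deposited table holds the authors' own comparison, with a log2 fold change and its standard error, a p-value and an adjusted p-value per gene, and the gene's name and type, per the file headers. Its columns are those of a DESeq2 results table. All 20666 log2 fold changes in the authors' deposited table equalled those of a DESeq2 fit of the deposited counts within 1e-06. The calls were not fully reproduced, with 2540 genes at an adjusted p under 0.05 in that DESeq2 fit and 2555 in the authors' deposited table. Gene names and types came from that table. Genome coordinates were not used here.

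Counts were used as deposited. Of 32883 genes, 12217 had no read in any library. Total counts per library were 51917449 and 45637881 for the controls and 56948370 and 48075810 for PE. Counts of the 2 control libraries differed from each other with a chi-square per degree of freedom of 161, and those of the 2 PE libraries with 23.4, so no library was a second copy of another. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3), with TMM factors and its default expression filter, a minimum count of 10 and a minimum total of 15. This kept 15257 genes. The factors were 1.03 and 0.999 for the controls and 0.986 and 0.982 for PE. The common dispersion was 0.0245, a biological coefficient of variation of 0.157, on 2 residual and 8.1 prior degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 over all tested genes counted as a change. CPM values are counts scaled by the TMM-adjusted library size, given as mean ± SD over the 2 libraries of a group, and log2 fold changes are PE over control with their standard error.

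Before the data were examined, the test, the thresholds, the alternatives, the rule for naming genes and 35 gene lists were fixed, and all alternatives were run. Where a symbol belonged to several identifiers, the most abundant was used, which concerns the 415 tested genes that share a symbol. Lists with at least 5 tested members, 33 of the 35, were tested with camera on the same model. Camera asks whether a list's genes rank higher or lower than other genes. It was run with its preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals, with adjustment over the 33 lists. The estimated form rests on the 2 residual degrees of freedom, so a call lost there need not mean that genes varied together. Fry was run beside camera. Its first p-value tests whether a list's genes move on balance one way, and its mixed p-value whether they change in either direction, without comparing them with other genes. Counts of members adjusted over the list alone are given beside those adjusted over all genes.

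Named genes followed a rule with 3 parts. The first took the 10 largest rises and 10 largest falls among changed genes with a mean log2 CPM of at least 1 and a symbol that is not an identifier. Clone names were treated as identifiers, although the written rule listed only some of their prefixes. The second part always named Nppa, Nppb, Acta1, Myh7, Myh6, Atp2a2, Rcan1 and Ankrd1. The third took up to 4 changed members of each list with the largest absolute log2 fold change, or the 2 most abundant members of a list with none. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

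The fit was tested on simulated counts of 15257 genes with the library sizes, means and dispersions of this comparison. It recovered 12% of genes changed 1.5-fold, 56% of those changed 2-fold, 92% of those changed 4-fold and 94% of those changed 8-fold. Of 155 calls, 8 were false, or 5.16%. In camera, a simulated list of 25 changed genes had p = 1.2e-55 with the preset correlation and p = 0.00322 with an estimated one. With the preset, 0% of 200 lists of unchanged genes had p below the threshold. Genes were simulated as independent, so this does not show how the preset behaves where genes vary together. In this simulation, 1.5-fold changes were therefore mostly missed. It changed 225 genes, against 2393 called in the data, so its recovery rates need not hold there. Of the called genes, 622 higher and 735 lower ones changed at least 2-fold, and the others passed with smaller changes.

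The alternatives were a DESeq2 1.42.0 Wald test, DESeq2 size factors, upper-quartile factors or library sizes alone in edgeR, no expression filter, a filter of 1 CPM in 2 libraries, and removal of the mitochondrial-genome genes or of the 10 most abundant genes. A replicate block, each library left out in turn, robust estimation, a test against a 1.5-fold change, an adjusted p threshold of 0.01, an estimated inter-gene correlation and a background of more abundant genes were also run. A crossed pairing was chosen after seeing the data. With 1 library left in a group, that library was assumed to vary like the other group.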

Results

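Transcript levels were measured by rRNA-depleted, strand-specific RNA-seq in cultured neonatal rat ventricular cardiomyocytes, a cell model of hypertrophic growth, with and without phenylephrine (PE). PE activates adrenergic receptors and is a standard inducer of cardiomyocyte hypertrophy in culture. Cells received 20 µM PE for 24 h (2 libraries) or no PE (2 libraries). Total counts were 51917449 and 45637881 in control replicates 1 and 2, and 56948370 and 48075810 in PE replicates 1 and 2. Mitochondrial-genome transcripts took 6.19% of counts in control replicate 1 and 11.7% in control replicate 2, against 4.61% and 4.76% in the PE libraries. The first principal component held 73.2% of the variance and separated PE from control libraries, and the second held 17.8%. It mainly separated control replicates 1 and 2, at -29.7 and 29.2, and to a lesser degree PE replicates 1 and 2, at 11.6 and -11.1. Correlation of log2 CPM across genes, which are not independent replicates, was 0.986 between the controls and 0.992 between the PE libraries, against 0.962 to 0.966 between groups.

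**Figure D1:**
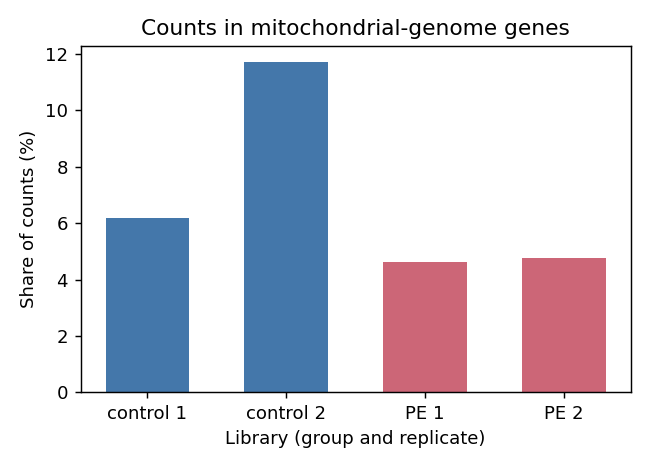
Share of counts in mitochondrial-genome genes (percent, vertical axis) for each of the 4 libraries, 1 bar per library. Control replicate 2 stands at 11.7% and the other 3 libraries between 4.61% and 6.19%.

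The series asks how PE changes the transcripts of these cells. The natriuretic peptide gene Nppa rose 19.8-fold with PE, from 172 ± 0.371 CPM to 3407 ± 223 CPM (SD, n = 2), and genes of cholesterol synthesis rose nearly as a whole. Several potassium channel genes fell. Camera with its preset correlation called fatty acid oxidation genes and markers of macrophages, endothelium and mesothelium lower as lists. With an estimated correlation it called none of them (adjusted p = 0.414, 0.414, 0.613 and 0.508), and the endothelial call was also lost without control replicate 1 (adjusted p = 0.0856) or PE replicate 1 (adjusted p = 0.0744). Of 15257 genes tested, 2393 changed, or 15.7%, with 1127 higher and 1266 lower. At least 2-fold differences were seen in 622 of the higher and 735 of the lower genes. The number of changed genes depended on which libraries entered. It was 4708 without control replicate 1, 4755 without control replicate 2, 1205 without PE replicate 1 and 1267 without PE replicate 2. With 1 library left in a group, the spread came from the other pair alone, and the control pair differed more than the PE pair.

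Among the index genes of hypertrophy, Nppa (ENSRNOG00000008176), Nppb (ENSRNOG00000008141), Acta1 (ENSRNOG00000017786) and Rcan1 (ENSRNOG00000001979) rose. Log2 fold changes were 4.31 ± 0.19 (SE) for Nppa, 2.19 ± 0.18 for Nppb, which encodes the second natriuretic peptide, 2.60 ± 0.23 for Acta1, skeletal alpha-actin, and 1.40 ± 0.16 for Rcan1, a calcineurin regulator (adjusted p = 2.07e-06, 4.61e-05, 6.45e-05 and 0.000318). Atp2a2 (ENSRNOG00000001285), the sarcoplasmic reticulum calcium pump, fell by 0.99 ± 0.18 on the log2 scale, from 4688 ± 338 CPM to 2355 ± 27 CPM (adjusted p = 0.00369, n = 2 each). Without PE replicate 1 its log2 fold change was -0.98 and no longer passed (adjusted p = 0.0599). Myh7 (ENSRNOG00000016983) and Myh6 (ENSRNOG00000025757), the beta and alpha myosin heavy chains, did not pass, at 0.26 ± 0.18 and -0.54 ± 0.22 (adjusted p = 0.409 and 0.132). Myh6 passed without a filter (adjusted p = 0.0122). Myh6 was at -0.41 without control replicate 1 and -0.66 without control replicate 2, and Myh7 was at 0.34 without control replicate 1. Those fits called them, but took the spread from the PE pair alone, so they add no support. Ankrd1 (ENSRNOG00000018598), a stretch-responsive titin-associated gene, was at 0.77 ± 0.24 (adjusted p = 0.0547) and did not pass. Ankrd1 was at 0.47 without control replicate 1 and 1.16 without control replicate 2, and was called both times with that same limit. It also passed with DESeq2 (adjusted p = 0.00813), without a filter (adjusted p = 5.63e-05) and with mitochondrial genes left out (adjusted p = 0.0481).

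**Figure D2:**
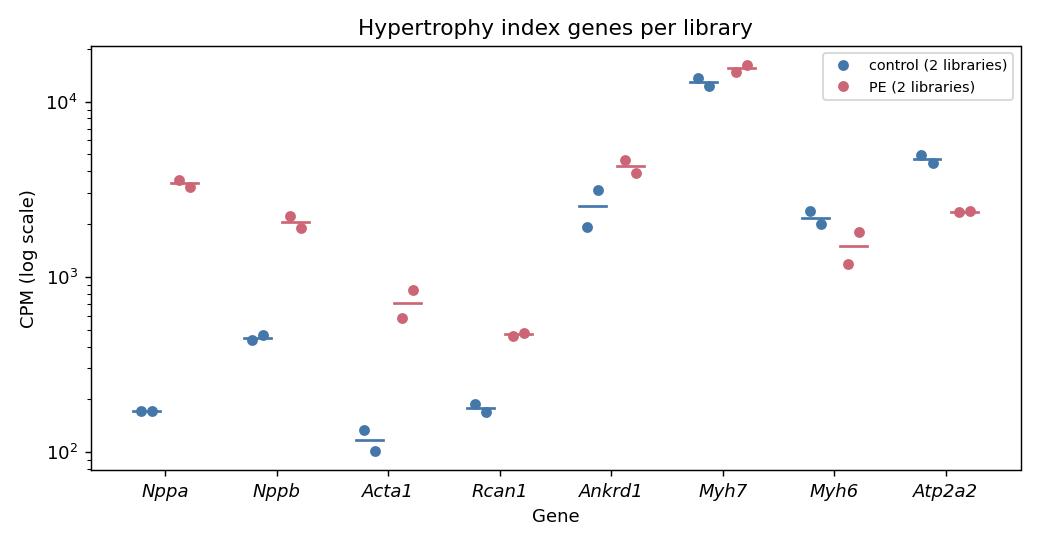
CPM per library on a log scale for 8 index genes of hypertrophy in 2 control and 2 PE libraries; points are libraries and short lines are group means. Nppa stands at a mean of 172 CPM in controls and 3407 CPM with PE, and Atp2a2 at 4688 CPM and 2355 CPM.

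Of the 22 hypertrophy markers, 11 rose, 1 fell and 10 did not pass, with 12 higher and 2 lower when adjusted over the list alone. Xirp2, a protein of the intercalated disc, rose from 63.4 ± 32.7 CPM to 1335 ± 320 CPM, and Fhl1, a LIM-domain protein of the sarcomere, from 183 ± 33.8 CPM to 1530 ± 89.4 CPM. The log2 fold change of Xirp2 was 4.40, and 5.05 without control replicate 2. The list's median log2 fold change was 0.84, and camera called it higher (adjusted p = 3.41e-16; adjusted p = 0.379 with an estimated correlation). The 27 measured genes of mature contraction and calcium handling were split, with 6 higher and 6 lower, or 7 and 8 adjusted over the list alone. Cardiac actin Actc1 rose by 1.53 ± 0.19. Hrc and Trdn, of the calcium store of the sarcoplasmic reticulum, fell by 2.15 ± 0.20 and 1.59 ± 0.32, and the myoglobin gene Mb fell by 1.35 ± 0.18 on the log2 scale. Trdn was at -0.88 without control replicate 2 and still passed (adjusted p = 3e-07). The list as a whole was not called (median -0.07, adjusted p = 0.76), and its median was 0.15 without control replicate 1 and 0.13 without control replicate 2. Reads shared among the actin genes Acta1, Actc1 and Acta2 make their single values uncertain.

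The largest rises were those of Scn3b, a sodium channel beta subunit, and Myh3, the embryonic skeletal myosin heavy chain, at log2 fold changes of 6.25 ± 0.24 and 6.15 ± 0.55. Myh3 had 7 and 1 counts in the controls and was at 7.91 without control replicate 1 and 5.46 without control replicate 2. Ckmt1, a mitochondrial creatine kinase, followed at 5.98, then Ramp3 at 5.74, calponin Cnn1 at 4.97, the skeletal calsequestrin Casq1 at 4.94, the bradykinin receptor Bdkrb2 at 4.89, Syt12 at 4.52 and Wfdc1 at 4.46. Casq1 rose from 4.45 ± 0.527 CPM to 137 ± 20.7 CPM and Bdkrb2 from 3.6 ± 1.03 CPM to 106 ± 1.19 CPM (SD, n = 2). Among the largest falls, Otof, otoferlin, fell by 5.83 ± 0.49 on the log2 scale. It had 15 and 1 counts in the PE libraries and was at -8.53 without PE replicate 1 and -5.03 without PE replicate 2. Other large falls were those of Rasd2 (-4.84), Dhrs7c (-4.75), Syt6 (-4.67), the retinoid receptor gene Rxrg (-4.29), Klhl33 (-4.22), Asb14 (-3.95) and B3gat1 (-3.53). Syt6, with 23 and 5 counts in the PE libraries, was at -5.98 without PE replicate 1 and -4.05 without PE replicate 2. Among the 10 largest rises and 10 largest falls the largest adjusted p was 7.54e-05, that of Myh3.

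Genes listed under ERK pathway feedback were higher as a list. That list also held transcription factor genes such as Etv4, so it is not one of negative feedback genes alone. Of 20 measured, 6 rose, 1 fell and 13 did not pass, with 7 higher and 1 lower adjusted over the list alone (median 0.19, adjusted p = 0.00134; adjusted p = 0.613 with an estimated correlation). The MAP kinase phosphatase genes Dusp8 and Dusp4 rose by 2.39 ± 0.22 and 1.53 ± 0.19, and Etv4, a transcription factor downstream of ERK, by 1.57 ± 0.19. The list's median was 0.46 without control replicate 1, 0.08 without control replicate 2, 0.31 without PE replicate 1 and 0.09 without PE replicate 2, and it was called each time. Of 24 immediate early transcription factors, 7 rose, 2 fell and 15 did not pass (9 and 2 adjusted over the list alone). Btg2 rose by 1.26 ± 0.16 and Nr4a3 by 1.14 ± 0.20, while Klf2 fell by 1.86 ± 0.26. That list was called higher (median 0.41, adjusted p = 0.0258; adjusted p = 0.58 with an estimated correlation), but not without control replicate 2 (adjusted p = 0.0733) or PE replicate 2 (adjusted p = 0.0745).

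Genes of adrenergic receptors and RGS proteins changed in both directions. Their list also held genes of G proteins, phospholipases, kinases and arrestins. Of its 23 measured genes, 4 rose, 4 fell and 15 did not pass, or 5 and 5 adjusted over the list alone. The receptor genes Adra1d and Adra1b fell by 3.16 ± 0.30 and 1.71 ± 0.22 on the log2 scale. Adra1d went from 8.65 ± 2 CPM to 0.959 ± 0.307 CPM. Rgs2, which shuts off G protein signals, rose by 2.4 ± 0.2, and Rgs6 fell by 1.34 ± 0.16. The list was not called (adjusted p = 0.834), and its median of 0.03 differed in sign from its mean of -0.08 and from the test.

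Of the 33 lists tested, cholesterol synthesis and uptake had the largest share of members that passed. Of its 25 genes, 24 rose and 1 did not pass, and all 25 rose adjusted over the list alone, with a median log2 fold change of 1.44 (adjusted p = 1.88e-33; adjusted p = 0.389 with an estimated correlation). Idi1, of isoprenoid synthesis, rose from 85.6 ± 30.7 CPM to 473 ± 102 CPM, Fdps from 229 ± 41.8 CPM to 1050 ± 12.2 CPM, and Msmo1, of sterol synthesis, from 60.9 ± 0.498 CPM to 234 ± 31.1 CPM. The corresponding log2 fold changes were 2.47 ± 0.26, 2.2 ± 0.19 and 1.94 ± 0.17 (adjusted p = 0.000186, 5.59e-05 and 6.64e-05).

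Of 28 fatty acid oxidation genes, 9 fell, 1 rose and 18 did not pass (10 and 2 adjusted over the list alone). Hadh, of beta-oxidation, fell by 1.95 ± 0.17 on the log2 scale, from 45.8 ± 0.366 CPM to 11.8 ± 0.597 CPM. Ech1 fell by 1.75 ± 0.17 and Pdk2, a kinase that restrains pyruvate dehydrogenase, fell by 1.47 ± 0.18. The list was called lower (median -0.41, adjusted p = 0.000113; adjusted p = 0.414 with an estimated correlation), and its median was -0.27 without control replicate 1. Among 45 nuclear-encoded respiratory chain genes, 2 fell and 43 did not pass, with 1 lower adjusted over the list alone (median -0.06, adjusted p = 0.365). These were Cox8b, which fell by 1.31 ± 0.21, and Ndufb10, which fell by 1.00 ± 0.30 and did not pass without control replicate 2 (-0.34, adjusted p = 0.136), PE replicate 1 (-1.04, adjusted p = 0.0506) or PE replicate 2 (-0.95, adjusted p = 0.0826). Without control replicate 1 the list was called lower (-0.18, adjusted p = 0.0291), and without control replicate 2 its median was 0.02 (adjusted p = 0.97).

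All 13 mitochondrially encoded protein genes had negative log2 fold changes and 4 passed, or 12 adjusted over the list alone (median -1.35, adjusted p = 0.00134; adjusted p = 0.643 with an estimated correlation). That size rested on control replicate 2, with 11.7% of its counts in mitochondrial-genome transcripts. Without it the median was -0.23 and the list was not called (adjusted p = 0.0933). Mt-nd5, which passed, fell by 1.56 ± 0.40 on the log2 scale, from 3807 ± 2779 CPM to 1292 ± 6.1 CPM, and was at -2.15 without control replicate 1 and -0.51 without control replicate 2 (adjusted p = 0.000467); DESeq2 did not call it (adjusted p = 0.158).

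Glycolytic genes were higher as a list. Of 22, 8 rose, 2 fell and 12 did not pass, with 10 and 2 adjusted over the list alone (median 0.39, adjusted p = 0.00132; adjusted p = 0.613 with an estimated correlation). The lactate exporter Slc16a3 rose from 20.5 ± 6.63 CPM to 187 ± 39.2 CPM. The phosphofructokinase genes Pfkp and Pfkl rose by 1.62 ± 0.17 and 1.5 ± 0.22, and Slc2a4, the insulin-responsive glucose transporter, fell by 1.54 ± 0.19. The list's median was 0.64 without control replicate 1 and 0.24 without control replicate 2, and it was called both times.

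None of the 20 cytosolic aminoacyl-tRNA synthetases (median 0.18, adjusted p = 0.167) or of the 66 cytosolic ribosomal proteins (median 0.12, adjusted p = 0.385) passed in edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 and 5, and DESeq2 called 1 in each. Log2 fold changes were positive in 19 of the 20 synthetases, whose median was 0.09 without control replicate 2. The most abundant members were Eprs at 0.16 ± 0.17 and Aars at 0.12 ± 0.18, and Rps2 at 0.19 ± 0.18 and Rplp0 at 0.16 ± 0.22. Without control replicate 1, Rps2 was at 0.37 and Rplp0 at 0.52 and both passed (adjusted p = 0.0271 and 0.000956), and without control replicate 2, Rplp0 was at -0.12. Of 42 ribosome biogenesis genes, 3 rose and 39 did not pass, with 1 higher adjusted over the list alone (median 0.19, adjusted p = 0.109), and 31 of the 42 had positive log2 fold changes. Rrp12, a factor of ribosomal subunit export, rose by 1.13 ± 0.20. Without control replicate 2 that list was called higher (0.31, adjusted p = 0.0112), and without control replicate 1 its median was 0.10 (adjusted p = 0.464).

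Translation factors were called higher close to the threshold (median 0.29, adjusted p = 0.0489; adjusted p = 0.508 with an estimated correlation), and were not called without PE replicate 1 (adjusted p = 0.0839) or with upper-quartile factors (adjusted p = 0.052). Of 39, 2 rose, 1 fell and 36 did not pass, with the same counts adjusted over the list alone. The member that fell was Eef2k, the kinase that inhibits elongation, by 1.06 ± 0.16, and it did not pass without PE replicate 1 (-1.02, adjusted p = 0.0607). Of 28 genes of the amino acid response and one-carbon metabolism, 2 rose, 3 fell and 23 did not pass (2 and 4 adjusted over the list alone). Ddit3, a stress transcription factor, fell by 1.03 ± 0.22, was at -0.67 without control replicate 2, and did not pass without PE replicate 2 (-0.998, adjusted p = 0.0647). The list's median was 0.003, its mean -0.04 and the test upward (adjusted p = 0.986), and the median was -0.04 with library sizes alone.

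Cytosolic heat shock genes were higher, with 7 of 21 up and 14 not passing, or 10 higher and 1 lower adjusted over the list alone (median 0.41, adjusted p = 0.00132; adjusted p = 0.414 with an estimated correlation). Hspb3, a small heat shock protein of muscle, rose by 2.08 ± 0.17 and Hspa4l by 1.15 ± 0.24. Of 24 endoplasmic reticulum folding genes, 1 rose, 1 fell and 22 did not pass, with the same counts adjusted over the list alone (median 0.01, adjusted p = 0.719), and the median was -0.08 without PE replicate 1 and 0.15 without control replicate 2. Edem1 rose by 0.66 ± 0.16 and Herpud1 fell by 0.70 ± 0.18, and neither passed without PE replicate 1 (0.64 and -0.63, adjusted p = 0.339 and 0.398) or PE replicate 2 (0.69 and -0.75, adjusted p = 0.256 and 0.236). Herpud1 was at -0.45 without control replicate 1 (adjusted p = 0.00991). In the atrophy and autophagy list, 7 of 27 fell, 1 rose and 19 did not pass, over all genes and adjusted over the list alone. Pink1, a kinase of mitochondrial quality control, fell by 1.62 ± 0.20, Klf15 fell by 1.58 ± 0.19 and Fbxo32, the ubiquitin ligase atrogin, fell by 1.37 ± 0.16 on the log2 scale. That list did not pass (median -0.18, adjusted p = 0.0532) but did without control replicate 2 (-0.27, adjusted p = 0.0112), with DESeq2 (adjusted p = 0.0178), with library sizes alone (adjusted p = 0.049) and without a filter (adjusted p = 0.0287). Without control replicate 1 its median was -0.05.

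Actin and tubulin cytoskeleton genes rose in 13 of 39 cases, with 1 lower and 25 not passing, or 14 and 1 adjusted over the list alone (median 0.32, adjusted p = 8.02e-06; adjusted p = 0.508 with an estimated correlation). Tuba1a rose from 242 ± 66.5 CPM to 1354 ± 22.4 CPM, a log2 fold change of 2.48 ± 0.22, and the actin-severing cofilin gene Cfl2 rose by 1.31 ± 0.17. Tubulin copies share sequence, so single tubulin values are uncertain. Of 33 extracellular matrix genes, 11 rose, 6 fell and 16 did not pass, with 13 and 8 adjusted over the list alone. Tgfb2 rose from 129 ± 2.29 CPM to 627 ± 12.5 CPM and Ctgf, connective tissue growth factor, by 1.85 ± 0.19. The list was called higher (median 0.14, adjusted p = 0.0315; adjusted p = 0.733 with an estimated correlation), but not without control replicate 2 (-0.01, adjusted p = 0.401) or PE replicate 2 (0.10, adjusted p = 0.065). Without control replicate 1 its median was 0.37. The fibroblast marker list had a median of -0.34.

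Ion channel and conduction genes changed in 19 of 30 cases. There were 6 higher and 13 lower, or 7 and 14 adjusted over the list alone. Gja5, connexin of conducting tissue, rose from 24.1 ± 0.171 CPM to 119 ± 2.26 CPM. The inward rectifier gene Kcnj3 fell by 3.06 ± 0.22 on the log2 scale, from 11.7 ± 0.418 CPM to 1.4 ± 0.116 CPM. As a list they did not pass (median -0.45, adjusted p = 0.0532), but did without control replicate 2 (-0.66, adjusted p = 0.00154), with DESeq2 (adjusted p = 0.0178), with library sizes alone (adjusted p = 0.049), without a filter (adjusted p = 0.0287), with the 1 CPM filter (adjusted p = 0.0338) and against abundant genes (adjusted p = 0.0265). Without control replicate 1 the median was -0.14.

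Secreted growth factors were divided, with 10 of 36 higher, 9 lower and 17 not passing, or 11 and 10 adjusted over the list alone. Hbegf, an EGF receptor ligand, rose from 11 ± 2.28 CPM to 76.7 ± 3.49 CPM and Bdnf by 2.27 ± 0.24, and the cytokine gene Ctf1 fell by 1.69 ± 0.29. The list was not called (adjusted p = 0.291), and its median of -0.008 differed in sign from its mean of 0.17 and from the test, and was 0.16 without control replicate 1. Of 31 inflammatory mediators, 6 rose, 3 fell and 22 did not pass (9 and 3 adjusted over the list alone). The cytokine genes Il6 and Lif rose by 2.98 ± 0.34 and 2.12 ± 0.22, and Ptgs2, of prostaglandin synthesis, by 2.53 ± 0.28. That list did not pass (median 0.11, adjusted p = 0.0532), but did without control replicate 2 (0.34, adjusted p = 0.00154) and without PE replicate 2 (0.24, adjusted p = 0.000149), with DESeq2 (adjusted p = 0.0178), with library sizes alone (adjusted p = 0.0468) and without a filter (adjusted p = 0.02). Without PE replicate 1 its median was 0.02. Macrophage markers, at a median of -0.66, went the other way. Of 27 interferon response genes, 2 rose, 2 fell and 23 did not pass, with 2 and 1 adjusted over the list alone (median -0.28, adjusted p = 0.365). Ifit1bl rose by 2.15 ± 0.23 and the transcription factor gene Irf7 fell by 2.00 ± 0.31, and was at -2.60 without PE replicate 2. Without PE replicate 2 that list was called lower (-0.31, adjusted p = 0.0426). Its median was -0.17 without control replicate 2 (adjusted p = 0.616), and without PE replicate 1 the test turned upward (adjusted p = 0.931).

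Cell cycle genes passed in 5 of 38 cases, 3 higher and 2 lower, with the same counts adjusted over the list alone (median 0.28, adjusted p = 0.075). Cyclin gene Ccnd1 rose by 1.32 ± 0.20 and the cyclin-dependent kinase inhibitor gene Cdkn1c fell by 2.22 ± 0.18. Without control replicate 2 the list was called higher (0.34, adjusted p = 0.0391), as it was without a filter (adjusted p = 0.0364). Of 25 replication-dependent histone genes, 1 fell and 24 did not pass, also adjusted over the list alone (median -0.36, adjusted p = 0.0709). It was Hist2h2ac, which fell by 0.95 ± 0.22 and did not pass without PE replicate 1 (-0.69, adjusted p = 0.315). The histone list was called lower without control replicate 2 (-0.48, adjusted p = 0.00846) and without PE replicate 2 (-0.48, adjusted p = 0.00491), and without a filter (adjusted p = 0.0367). Its median was -0.18 without control replicate 1 (adjusted p = 0.427) and -0.23 without PE replicate 1 (adjusted p = 0.325). Of 19 circadian clock genes, 1 rose, 1 fell and 17 did not pass, with the same counts adjusted over the list alone (median -0.17, adjusted p = 0.719), and the median was -0.05 without control replicate 1 and -0.28 without control replicate 2. Nfil3 rose by 1.30 ± 0.21, and Dbp fell by 0.83 ± 0.17 but did not pass without PE replicate 1 (-0.75, adjusted p = 0.242) or PE replicate 2 (-0.89, adjusted p = 0.116).

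Markers of macrophages, mesothelium and endothelium were lower with PE as lists. All 20 macrophage and leukocyte markers had negative log2 fold changes, and 9 fell, or 14 adjusted over the list alone (median -0.66, adjusted p = 0.00012; adjusted p = 0.414 with an estimated correlation). Cd74 fell by 2.01 ± 0.42 on the log2 scale, and Mrc1 fell by 0.93 ± 0.19, from 33.6 ± 6.85 CPM to 17.6 ± 0.0171 CPM. Mrc1 did not pass without PE replicate 1 (adjusted p = 0.0982) or PE replicate 2 (adjusted p = 0.0957). Of 14 epicardial and mesothelial markers, 6 fell, 2 rose and 6 did not pass, with 7 and 2 adjusted over the list alone (median -0.66, adjusted p = 0.0161; adjusted p = 0.508 with an estimated correlation), and the median was -0.41 without control replicate 1. Upk3b, a mesothelial gene, fell by 1.75 ± 0.21. Of 18 endothelial markers, 6 fell, 1 rose and 11 did not pass, with 11 and 1 adjusted over the list alone (median -0.62, adjusted p = 0.0258; adjusted p = 0.613 with an estimated correlation). That list was not called without control replicate 1 (-0.48, adjusted p = 0.0856) or PE replicate 1 (-0.59, adjusted p = 0.0744). Emcn and Erg fell by 1.54 ± 0.27 and 1.10 ± 0.20, and Flt1, a VEGF receptor gene, rose by 1.15 ± 0.17.

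Fibroblast markers were not called as a list (median -0.34, adjusted p = 0.219), and their median was -0.09 without control replicate 1. Of 19, 7 fell, 2 rose and 10 did not pass, with 7 and 3 adjusted over the list alone. Dpt fell from 111 ± 27.4 CPM to 28 ± 0.587 CPM, and Fbln2 rose from 74.9 ± 31.5 CPM to 270 ± 14.9 CPM. Smooth muscle and pericyte markers went both ways, with 6 of 15 higher, 5 lower and 4 not passing, or 6 and 7 adjusted over the list alone. Their median of -0.35 differed in sign from their mean of 0.34 and from the test (adjusted p = 0.133), and with DESeq2 the test, again upward against a median of -0.41, passed (adjusted p = 0.0439). Cnn1 rose by 4.97 ± 0.20 and Mcam by 1.58 ± 0.16, and Lmod1 fell by 1.5 ± 0.29. None of 11 glial and neuronal markers passed in edgeR or DESeq2, over all genes or, in edgeR, adjusted over the list alone, and 5 had an unadjusted p under 0.05 in edgeR (median -0.06, adjusted p = 0.777). Their 2 most abundant members were Ncam1 at 0.27 ± 0.16 and Dbh at 0.45 ± 0.18, and Dbh passed without control replicate 2 (0.48, adjusted p = 0.037). Lists with under 5 tested members were not put to camera. All 3 erythroid markers measured fell, over all genes and adjusted over the list alone. They included Hba-a2, at under 1 CPM in both groups, and Gypc, which fell by 0.68 ± 0.16 and did not pass without PE replicate 1 (-0.71, adjusted p = 0.301) or PE replicate 2 (-0.63, adjusted p = 0.376). Hba-a2 was at -2.00 ± 0.60 and did not pass without any 1 of the 4 libraries (adjusted p = 0.0685 and 0.099 without control replicates 1 and 2, 0.418 and 0.16 without PE replicates 1 and 2). Of 3 long noncoding RNAs measured from the list, the telomerase RNA gene Terc fell by 1.29 ± 0.31, with 2 lower adjusted over the list alone. Terc did not pass without PE replicate 1 (-1.14, adjusted p = 0.128).

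**Figure D3:**
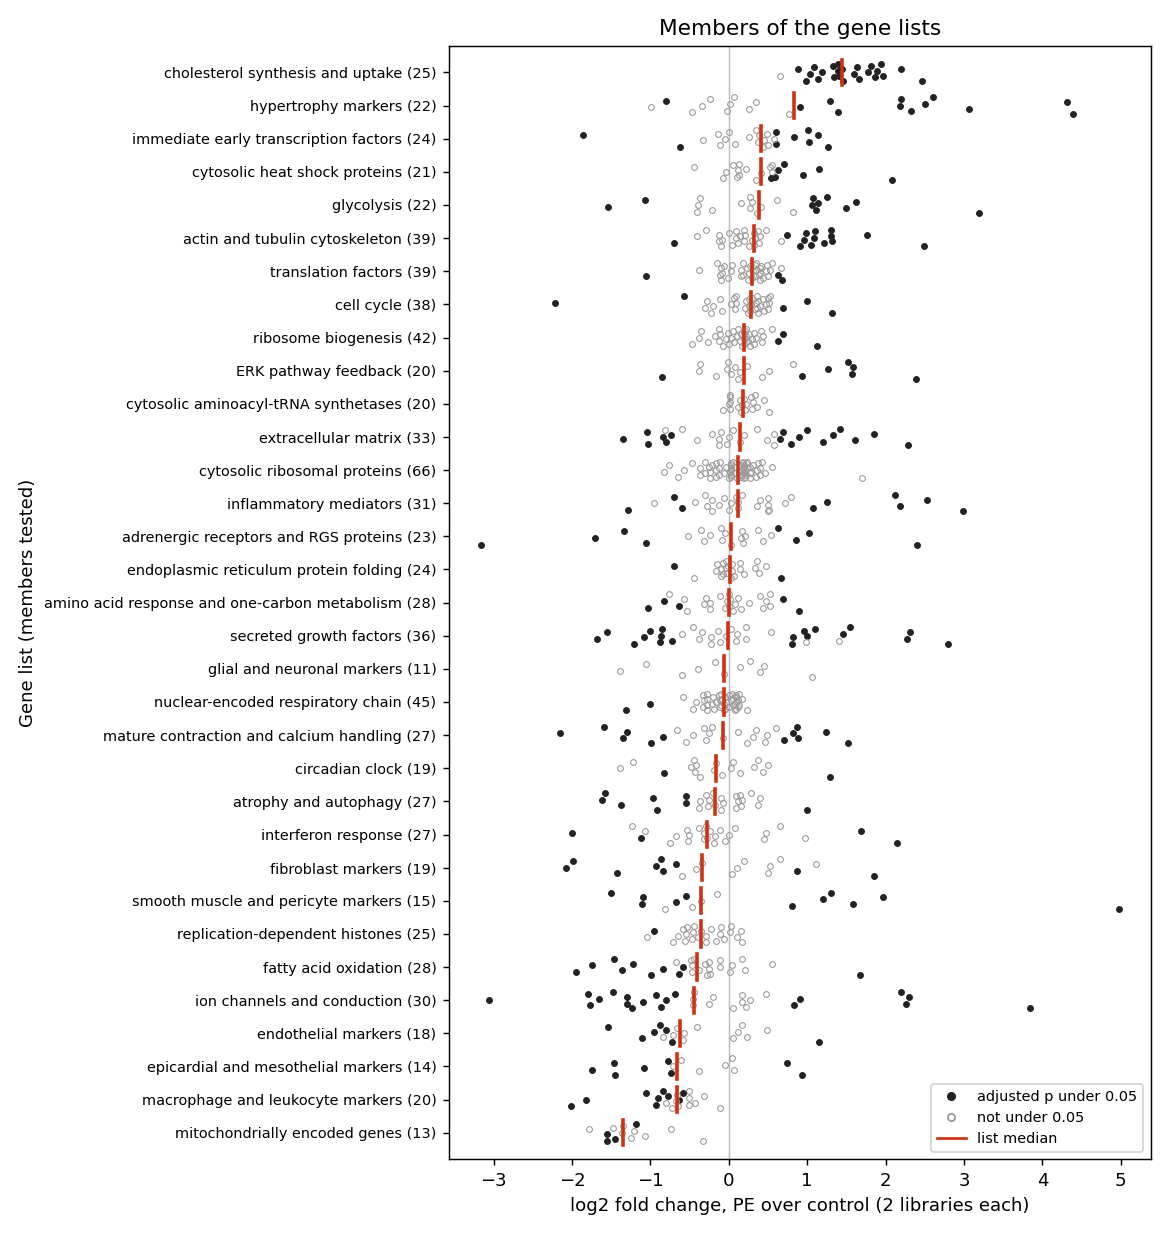
Log2 fold change of PE over control (horizontal axis, 2 libraries each) for every tested member of 33 gene lists; filled points have adjusted p under 0.05, open points do not, and red bars are list medians. The cholesterol list, with a median of 1.44, lies entirely to the right of 0, and the macrophage and leukocyte list, with a median of -0.66, entirely to the left.

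Camera with its preset correlation called 14 of the 33 lists, 9 higher and 5 lower. With an estimated correlation it called 0, the lowest adjusted p being 0.379, and 2 had an unadjusted p under 0.05. That form of camera rests on the 2 residual degrees of freedom. For hypertrophy markers the estimated correlation was 0.001, below the preset 0.01, yet the unadjusted camera p went from 2.07e-17 to 0.0115. A call lost there therefore need not mean that genes varied together. Fry called 2 lists as moving on balance one way, with a lowest adjusted p of 0.0336, and 27 as changing in either direction. The 9 lists called with the preset correlation whichever library was left out were hypertrophy markers, ERK feedback, fatty acid oxidation, glycolysis, cholesterol synthesis, heat shock genes, the cytoskeleton, and the macrophage and mesothelial markers.

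By gene class, 2287 of 13877 protein-coding genes changed (16.5%), 1083 higher and 1204 lower. Of 407 genes classed as long noncoding, 57 changed (14%), 20 higher and 37 lower. That class took in the deposited types lincRNA, antisense, sense intronic and processed transcript. The last included changed entries under protein-coding gene names, such as Itgb5 and Cd93, so the class is not purely long noncoding RNA. The odds ratio of protein-coding against long noncoding genes was 1.21 (95% interval 0.91 to 1.64), and a two-sided Fisher exact test gave p = 0.197. Genes are not independent replicates, so this test, here and below, only describes the list of calls. In the same Fisher exact test the odds ratio was 1.95 without control replicate 1 (p = 3.15e-09), 1.84 without control replicate 2 (p = 3.41e-08) and 1.53 without PE replicate 2 (p = 0.0308). The Fisher exact test also passed with DESeq2 calls (odds ratio 1.76, p = 7.48e-05) and without a filter (3.40, p = 1.36e-34), and with the 1 CPM filter the odds ratio turned to 0.739 (Fisher exact p = 0.0709). Pseudogenes changed in 23 of 313 cases and small nucleolar RNAs in 2 of 252.

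The authors' deposited table of their own comparison calls 2555 genes at the same threshold, 1238 with positive and 1317 with negative log2 fold changes. Of these, 2272 were also called by edgeR, which is 94.9% of the edgeR calls, and all 2272 had the same sign. Only 121 edgeR calls were absent from the calls in the authors' deposited table, and 283 of the authors' calls were not called by edgeR. The number shared was 1133 without PE replicate 1 and 1202 without PE replicate 2. Log2 fold changes in the authors' deposited table and in edgeR had a Pearson correlation of 0.9997 across genes, which are not independent replicates. In the authors' deposited table, Nppa has a log2 fold change of 4.31, Atp2a2 of -0.99 and Ankrd1 of 0.77, the last with an adjusted p of 0.00782.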

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

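The crossed pairing and the comparison of fatty acid oxidation and respiratory chain lists without each library were chosen after seeing the data; the other alternatives were not. Of 133 changed genes named by rule, 94 kept direction and call under all of the up to 13 alternatives run for single genes and 113 under those of them with 4 libraries. Robust estimation, the crossed block, the 1.5-fold test and the 0.01 threshold were run for counts of genes only. Of 14 called lists, 9 kept theirs under the alternatives run for lists, with the estimated correlation set aside, which left 0. Changed genes numbered 973 against a 1.5-fold change and 1260 at an adjusted p under 0.01, both stricter by construction. With 1 library left out, changed genes ranged from 1205 to 4755, higher genes from 604 to 2398, lower genes from 601 to 2389, and calls shared with the authors' deposited table from 1133 to 2488. Without a PE library the spread came from the wider control pair, which gave the low counts, and without a control from the narrower PE pair. Replicate numbers are shared by both groups, but nothing says that they pair the libraries, and deviations of same-numbered libraries correlated at -0.229. With replicate number as a block, 1964 genes changed, 913 higher and 1051 lower. Crossing the pairs (a crossed replicate block) gave 4677, 2270 higher and 2407 lower. The odds ratio of calls by gene class, 1.21, was 1.76 with DESeq2, 3.40 without a filter, 0.739 with at least 1 CPM in 2 libraries, 0.927 with the replicate block and 1.11 to 1.95 with 1 library left out; the cause was not tested. Lists never called in the main comparison turned in test direction as follows, given as medians. The amino acid response list was at 0.005 with DESeq2, -0.045 with library sizes alone, 0.003 without a filter, -0.008 with the 1 CPM filter, 0.007 with the replicate block, 0.003 against abundant genes, and -0.134 to 0.144 with 1 library left out. Glial and neuronal markers were at 0.144 with DESeq2, 0.139 against abundant genes and -0.137 to 0.171 with 1 library left out. With 1 library left out, adrenergic genes ranged from -0.057 to 0.14, ribosomal proteins from 0.004 to 0.178, interferon genes from -0.313 to -0.167, Aars from -0.076 to 0.349 and Rplp0 from -0.117 to 0.52; the cause was not tested. Translation factors lost their call with upper-quartile factors (adjusted p = 0.052), the 1 CPM filter (0.07), mitochondrial genes left out (0.0504) and abundant genes as background (0.0697). Genes under the count filter were not tested, and 2 libraries per group recovered 56% of simulated 2-fold changes.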

Other observations

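The tests of the mitochondrial, marker, cholesterol and fatty acid patterns below were chosen after those results were seen, and the bounds for the other cell types, the fatty acid pattern and the skeletal muscle and receptor lists were made stricter after their tests; the skeletal muscle and receptor lists were written after the largest rises were seen, but before their own members were looked at.

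Skeletal muscle genes and receptor genes stood among the largest rises, and each idea was tested on other members of its class. Of 29 further skeletal muscle genes measured, 7 rose, 7 fell and 15 did not pass (median 0.23). Myl1, a fast skeletal myosin light chain, rose by 2.48 ± 0.45 (SE) and Lmod3, a leiomodin of the thin filament, fell by 1.34 ± 0.31, in edgeR with 2 libraries per group. Both were low, Myl1 going from 0.21 to 1.19 CPM and Lmod3 from 3.08 to 1.21 CPM. The hypothesis that skeletal muscle genes rise as a group found no backing in camera (p = 0.675, adjusted p = 0.737 over 2 lists, and p = 0.682 with an estimated correlation), and members went both ways. The list mixed genes already abundant in control cells, such as Tnni1 (714 CPM) and Nrap (475 CPM), with genes near the floor, such as Myh4 (0.148 CPM). It therefore could not decide whether skeletal genes nearly silent in control cells, such as Myh3, rise as a group. Receptors of vasoactive and inflammatory ligands also changed in both directions, with 8 of 49 higher and 10 lower (median -0.004, mean -0.13). Tnfrsf12a, the TWEAK receptor gene, rose from 44.8 ± 6.15 CPM to 252 ± 8.39 CPM, Lpar3 by 1.76 ± 0.19 and S1pr1 from 92.5 ± 9.37 CPM to 223 ± 18.2 CPM. The endothelin receptor gene Ednra fell from 180 ± 9.11 CPM to 74.6 ± 4.01 CPM, Tbxa2r fell by 2.01 ± 0.33 and Lpar1 fell by 1.18 ± 0.17. A common rise of these receptors was not seen either (p = 0.737 in camera, p = 0.819 with an estimated correlation). Both lists left out the genes already named. The examples were chosen after their values were seen, and each passed without each of the 4 libraries.

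Fatty acid oxidation genes and nuclear-encoded respiratory chain genes were compared as lists, since most members of both encode mitochondrial proteins. The fatty acid oxidation list also held genes such as Lpl and Ppara, whose proteins are not mitochondrial. Had nuclear genes for mitochondrial proteins fallen in general, the lists would have moved alike. The fatty acid oxidation median lay 0.346 lower (log2 difference -0.346), and a two-sided permutation test of list membership gave p = 5e-05 over 100000 permutations. Genes are not independent, so that p-value is too small to the extent that they vary together. Without control replicate 1 the medians were -0.271 and -0.183, and their difference of -0.089 did not pass (permutation p = 0.314), while it passed without each of the other libraries (highest permutation p = 0.00012). A fall of nuclear genes for mitochondrial proteins in general cannot be told apart from a fall of fatty acid oxidation genes alone, because the difference between the lists depended on control replicate 1.

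Mitochondrially encoded transcripts were lower with PE, at a median of -1.35, and called as a list with the preset but not with an estimated correlation (adjusted p = 0.643). Most of that size traces to control replicate 2: without it the median was -0.228 and the list was no longer called (adjusted p = 0.0933), against -1.98, -1.37 and -1.29 without each of the other libraries. Mitochondrial DNA carried into that library would raise all of the mitochondrial genome, but Mt-nd6 was only 0.316 higher on the log2 scale in control replicate 2 than in control replicate 1 and the summed tRNAs 0.49, against a median of 1.66 for the other 12 protein genes. A fall with PE of a smaller size may remain, because both PE libraries, at 4.61% and 4.76%, lay below control replicate 1 at 6.19%. What set control replicate 2 apart was not tested.

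Macrophage, endothelial and mesothelial marker lists were called lower with PE by camera with its preset correlation but not with an estimated one (adjusted p = 0.414, 0.613 and 0.508), and the endothelial list was not called without control replicate 1 (adjusted p = 0.0856) or PE replicate 1 (adjusted p = 0.0744). The macrophage and leukocyte median was -0.657 or lower under all 5 other scalings, so the choice among them does not explain it. These scalings left the median log2 fold change of all tested genes between -0.0538 and 0.0028. A larger scaling error could therefore not show in them. A lower share of macrophage and leukocyte RNA cannot be told apart from lower transcription of these genes: all 20 markers had negative log2 fold changes, but that count was seen before its test and restates the pattern, with the most abundant, Lyz2, going from 156 ± 15.2 CPM to 109 ± 20.4 CPM without passing. A lower share of all other cell types together cannot be told apart from changes in single types: the 5 lists did not separate in a permutation test of ranks (p = 0.197; p = 0.264 without Des, Cnn1 and Abcc9), which does not show that they are alike, and neither the fibroblast list was called nor the smooth muscle list, whose members passed in both directions. A direct effect of PE on these cells, in a culture from which attaching cells had been removed by plating, was not tested.

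Cholesterol synthesis genes were higher with PE, at a median of 1.44. Camera called them as a list with the preset but not with an estimated correlation (adjusted p = 0.389). Under 5 other scalings the lowest median was 1.393, so the choice among them does not explain the rise. Those scalings kept the median log2 fold change of all tested genes between -0.0538 and 0.0028. A larger scaling error was therefore not tested. A single library out of place would lower the list's median when left out, but the lowest of 4 was 1.398 and the highest 1.68. An effect of PE on this pathway may be a hypothesis that these tests leave standing. Differences between dishes, such as density or medium, run with the groups and were not tested.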
